A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

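Transcript levels were measured on single-colour Affymetrix Yeast Genome 2.0 arrays with biotin-labelled RNA from lager yeast strain CB11, in samples of 5 times after pitching. The values are signal intensity per probe set on a linear scale, as deposited by the authors in a table of all 14 arrays. The software named is GCOS 5.0, per the submitters' processing notes. The target to which arrays were scaled is not given in the sources used here. Medians of the deposited signal over all probe sets were 31.2, 35.0 and 37.6 for the 8 h arrays, 35.7 and 32.9 for 30 h, 22.6, 25.4 and 27.4 for 60 h, 30.9, 31.9 and 27.6 for 80 h and 38.7, 37.8 and 37.1 for 102 h, each in the order of the replicate numbers. Because these medians spanned 0.777 on the log2 scale, above a tolerance of 0.2 set beforehand, the values were quantile normalized between arrays, and the authors' scale as deposited served as an alternative.

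The table held 10928 probe sets, of which 166 were controls. A platform annotation named 7244 for exactly 1 gene and 1 for several, and left 3517 non-control probe sets unnamed here. Symbols were updated through gene numbers with a gene table of assembly R64, used for names only, so no coordinates are given. By this, 5498 probe sets belonged to 5449 S. cerevisiae genes and 1746 to genes of another organism. Symbols were equal in both tables for 99.8%. The background was planned from fission yeast probe sets with systematic names. The annotation held 0 of these, so the planned fallback applied: the dimmer part of all probe sets on each array, split at the median, with its 95th percentile, a signal of 22.1, as the threshold and its median of 5.58 as the floor for log2 values. A probe set was tested when at least 2 arrays of some time were above that threshold. Of the 5338 that passed, 110 are marked by the manufacturer as shared between transcripts (names ending in _s_at or _x_at). Where a gene had several tested probe sets (40 genes), lists and named genes used the brightest, and the sets of 2 such genes passed the test in opposite directions.

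Tests used limma 3.58.1 in R 4.3.3. A linear model with the 5 times was fitted to the log2 values of all 14 arrays, with an intensity trend in the moderated variance. The moderated F-test asked for any change over time, and 5 comparisons were tested: each time against the one before, and 102 h against 8 h. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Errors after a log2 change are its standard error from this fit. Where a probe set was below background on all arrays of 1 time, its fold is given as a lower bound, against the mean of the higher of its own signal and the background threshold on each of those arrays. Gene lists, 45 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry. Lists called in the comparisons in time order numbered 20, 18, 13, 10 and 17, and with an estimated correlation 1, 0, 0, 0 and 0. Fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes.

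Genes named in the text follow a rule fixed beforehand. It takes, for each comparison, the 8 largest rises and 8 largest falls past the test whose arrays do not overlap and that are above background on every array of a group. It adds up to 4 members of each described list, those with the largest change past the test or, where none passes, the largest change, and 50 genes named in advance. Each is annotated to a single gene, though the probe sets of PAU2 and PAU5 are marked as shared.

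The steps were tested on simulated data in which 200 of 5338 probe sets were changed by known amounts. A log2 change of 1 was recovered in 59.7% of cases for 30 h against 8 h, 64.2% for 60 h against 30 h, 73.1% for 80 h against 60 h and for 102 h against 80 h, and 68.7% for 102 h against 8 h. A log2 change of 0.5 was recovered in 13.4% to 25.4% of cases, and false calls made up 3.01% to 5.65% of calls. Noise was drawn independently per probe set, with the same spread at all times and no deviation shared across an array. The rates may therefore not hold for the real arrays. Replicates were taken from the numbers in the labels. No arrays held identical values. All samples came from 1 vessel, and nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Array precision is limited by the number of arrays, and the brightest signals can be compressed.

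Other settings chosen beforehand were the authors' scale, centring each array on its S. cerevisiae median, other floors, other filters on dim probe sets, no intensity trend, a fit on the arrays of both times alone, the replicate number as a block, a threshold of 0.01, leaving out each array, the mean of all probe sets of a gene, leaving out shared probe sets, and other set tests. A block for chip lot, fluidics station or scan day was planned and not run, because the experiment files as used here state the chip type only. Chosen after seeing the data were leaving out the 3 arrays whose mean log2 5′ to 3′ ratio lay over 0.75 below the median array, that ratio as a covariate, and the probe sets of the other organism as background. Fits that left out arrays kept the normalization, floor and filter made on all 14 arrays.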

Results

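Lager yeast strain CB11 was followed through a full-scale brewery fermentation, and its transcript levels were measured in samples drawn 8, 30, 60, 80 and 102 h after pitching, the addition of yeast to wort. The title of the series places the question on carbohydrate metabolism as the wort sugars are used. Total RNA was hybridised to 14 single-colour Affymetrix yeast arrays, 3 at each time except 30 h, which had 2. The labels give the organism as Saccharomyces cerevisiae, and lager yeasts are hybrids that also carry a genome from a related species, so the signal of a probe set may hold transcripts of both parents. The median deposited signal per array lay between 22.6 and 38.7. Between 94.4% and 96.7% of the 5498 probe sets for S. cerevisiae genes were above background on an array. The threshold was taken from the dimmer part of all probe sets after normalization. This share and its evenness therefore follow largely from that rule and do not measure detection. The number of arrays limits the precision. All samples came from 1 vessel, so p-values measure only the spread between these samples.

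The 5′ to 3′ signal ratio of 6 control transcripts, a measure of RNA integrity, set 3 arrays apart. Its mean on the log2 scale was -3.30 for 8 h replicate 1, -4.08 for 60 h replicate 1 and -1.66 for 60 h replicate 2, against -0.736 to -0.364 for the other 11 arrays. Counts without these 3 arrays are therefore given beside each gene group that involves 8 h or 60 h. Such fits keep only replicate 3 at 60 h, and replicates 2 and 3 at 8 h. For 60 h they rest on that 1 array, with a spread taken from the other times. Larger counts in them are therefore no independent support. The other arrays were not alike in every control. The deposited 5′ signal of 18S ribosomal RNA was 860 and 1380 on 8 h replicates 2 and 3. On the remaining arrays without low 5′ signal it ran from 3500 to 8870. The source of this difference was not tested, and it cannot be separated from time in comparisons with 8 h. Correlations between arrays of the same time ran from 0.903 to 0.994. The array 30 h replicate 2 correlated at 0.986 and 0.987 with 8 h replicates 2 and 3, and at 0.975 with 30 h replicate 1. A principal component analysis placed the 8 h arrays between -44.4 and -32.5 on the first component (43.5% of the variance) and the 80 h and 102 h arrays between 19.9 and 22.4. The second component (27.6%) was highest for 60 h replicate 1, at 50.5.

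**Figure D1:**
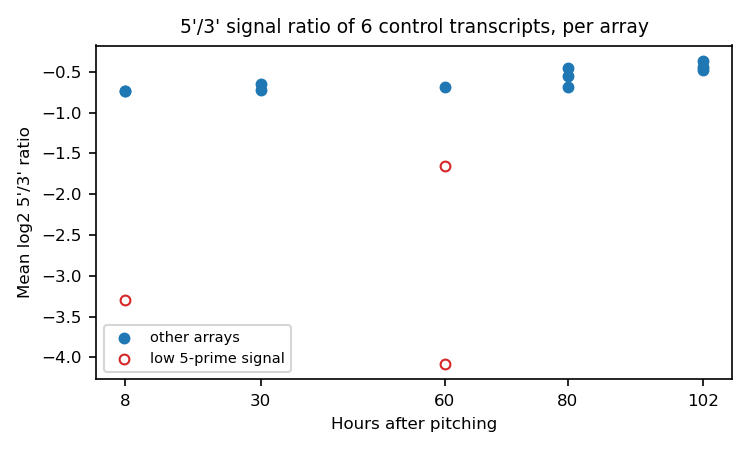
Mean log2 ratio of 5′ to 3′ signal over 6 control transcripts (vertical axis) against hours after pitching (horizontal axis), 1 point per array. Open points are the 3 arrays with low 5′ signal, at -3.30, -4.08 and -1.66, and the other 11 arrays lie between -0.736 and -0.364.

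Most measured genes changed during the fermentation. Of 5338 probe sets tested, covering 5298 genes, 3657 (68.5%) passed the moderated F-test over the 5 times, and 4367 (81.8%) did so without the 3 arrays of low 5′ signal. Among the 1881 probe sets that also spanned at least 2-fold, 654 had their highest mean at 8 h, 132 at 30 h, 410 at 60 h, 270 at 80 h and 415 at 102 h. When the 3 arrays were left out the set held 1815 probe sets, of which 663 were highest at 8 h and 318 at 60 h.

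The main sugar-use genes followed separate courses. The maltose permease gene MAL31 gave mean signals of 5000 at 8 h and 5410 at 30 h, then 2470, 2850 and 2570 at 60, 80 and 102 h. Signals of the maltase gene MAL32 were 8700 at 8 h and 5600 at 102 h. HXT4, a hexose transporter gene, went from 1180 at 8 h to 90.9 at 60 h and 112 at 102 h, while HXT5, a transporter gene known from slowly growing cells, went from 183 to 1150 and 732 at the same times. For FBP1, the fructose-1,6-bisphosphatase of gluconeogenesis, the means were 68.0, 71.7, 265, 1100 and 1240 in time order. The main alcohol dehydrogenase gene ADH1 stayed between 4550 and 4960 at all times (F-test adjusted p = 0.885). The invertase gene SUC2 gave 6590 at 8 h and 5720 at 102 h (F-test adjusted p = 0.109). HXT6 and MAL12 have no probe set for a single gene and FLO1 was below background, so none of the 3 was tested.

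**Figure D2:**
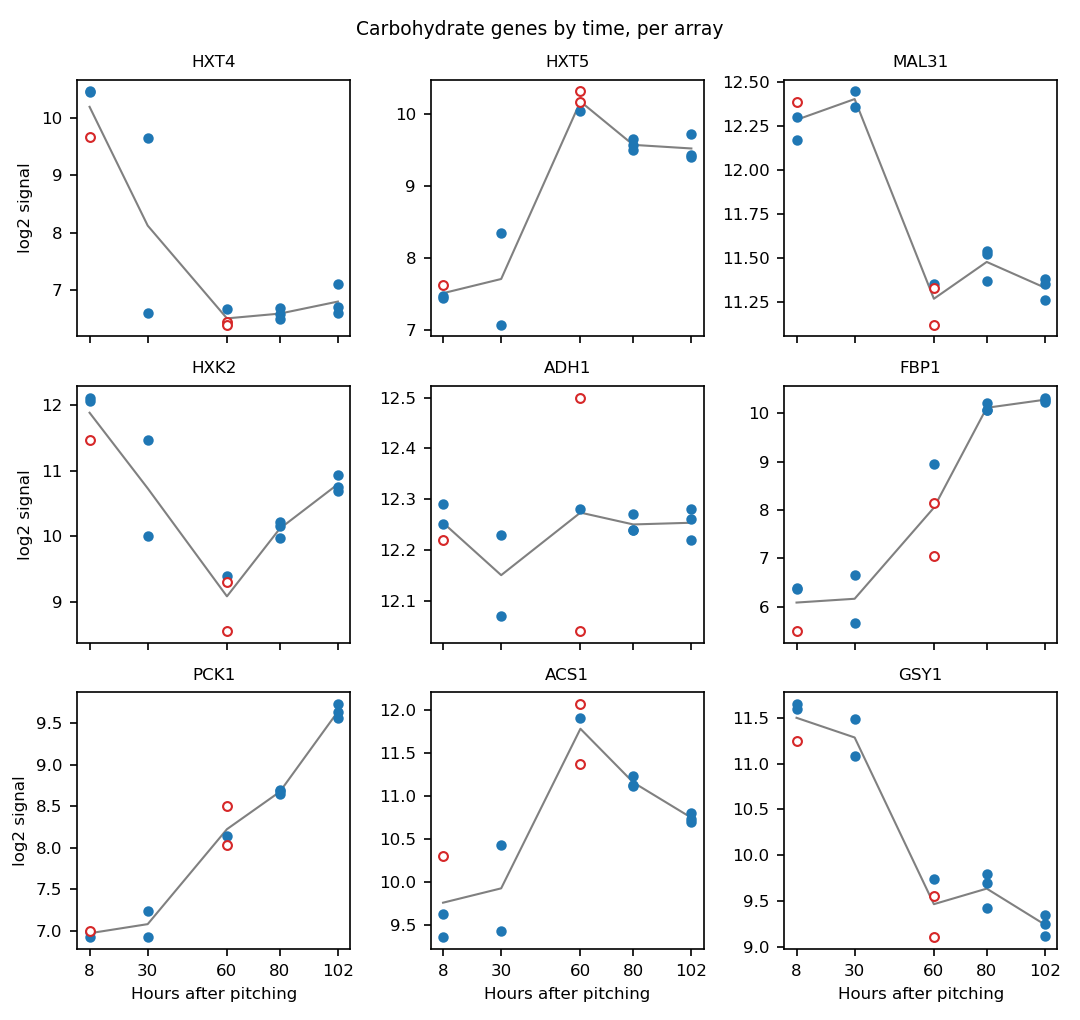
Normalized log2 signal (vertical axes, each with its own range) of 9 carbohydrate genes against hours after pitching, 1 point per array, with open points for the 3 arrays of low 5′ signal and lines through the group means. HXT4 and GSY1 are highest at 8 h, HXT5 and ACS1 at 60 h and PCK1 at 102 h, while all ADH1 values lie between 12.04 and 12.50.

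From 8 h to 30 h (n = 3 and 2 arrays), 6 genes rose and 7 fell. ARG1, argininosuccinate synthetase, rose by 1.85 ± 0.23 (log2 change ± SE, limma adjusted p = 0.0097), the arginine gene ARG3 by 1.35 ± 0.22 (adjusted p = 0.030) and LYS20, homocitrate synthase of lysine synthesis, by 0.77 ± 0.14 (adjusted p = 0.038). FAT3 rose by 1.74 ± 0.25, IZH1, a zinc homeostasis gene, by 1.16 ± 0.18, and MET30, a regulator of sulphur metabolism, by 0.85 ± 0.14. The serine and threonine deaminase gene CHA1 fell by 1.38 ± 0.24 (adjusted p = 0.038), the proline oxidase gene PUT1 fell by 1.19 ± 0.22 (adjusted p = 0.048) and the aromatic aminotransferase gene ARO9 fell by 1.15 ± 0.18 (adjusted p = 0.030). BUD8 fell by 1.04 ± 0.18, SLT2, the cell integrity kinase, fell by 0.98 ± 0.16, OCA2 fell by 0.94 ± 0.17 and NAB2, a binder of poly(A) RNA, fell by 0.78 ± 0.14.

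These 6 rises and 7 falls were all that passed over the 5338 probe sets, and 338 higher and 543 lower probe sets had an unadjusted p under 0.05. With the 3 arrays of low 5′ signal left out, of which 1 is an 8 h array, 215 probe sets were higher and 219 lower, including all 13. On the authors' scale as deposited, which moved the median of all probe sets by -0.14, 17.1% of the calls were higher, against 46.2% here and 64.3% with each array centred on its S. cerevisiae median. The calls rest on few arrays: none passed in either direction without 30 h replicate 1 or in a fit on the arrays of both times alone (all 13 genes at adjusted p = 0.48), while without 30 h replicate 2 there were 126 higher and 175 lower, and without 60 h replicate 1 there were 75 and 85. Leaving out 8 h replicate 2 or 3, 60 h replicate 2 or any array of 80 h or 102 h left 1 to 3 higher and 0 or 1 lower, and without 8 h replicate 1 none was lower. Calls also ended for LYS20 and MET30 on the authors' scale (adjusted p = 0.059 and 0.061), for CHA1, PUT1 and NAB2 with centred arrays (0.052, 0.067 and 0.078), for PUT1 without a filter on dim probe sets (0.057), and without an intensity trend for LYS20, CHA1, PUT1, OCA2 and NAB2 (0.054, 0.054, 0.072, 0.054 and 0.064). With the replicate number as a block, 1 probe set was higher and 0 lower. CHA1 stood at -0.91 without 30 h replicate 1.

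Some gene lists were called by camera at the preset correlation while few or none of their members passed. Of 38 measured stress genes under the transcription factors Msn2 and Msn4, 0 passed over all probe sets, 13 were higher when adjusted over the list alone, and the median change was 0.44 (camera adjusted p = 1.7e-12, and adjusted p = 0.058 with an estimated correlation). HSP26, a small heat shock protein, stood at 1.38 ± 0.47 (adjusted p = 0.18). Without the 3 arrays of low 5′ signal, 17 of these genes were higher, HSP26 by 0.92 (adjusted p = 0.041), and by 0.93 with the 5′ to 3′ ratio as a covariate (adjusted p = 0.028), but it stood at 0.81 without 30 h replicate 1. Among 35 genes of mitosis and cytokinesis, 0 passed and 18 were lower when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 4.5e-09, and adjusted p = 0.11 with an estimated correlation). Values were -1.32 ± 0.32 for BUD4 (adjusted p = 0.085) and -1.22 ± 0.33 for the cyclin gene CLB2 (adjusted p = 0.10), and 14 genes of the list were lower without the 3 arrays. BUD4 passed without the 3 arrays (-1.20, adjusted p = 0.045) and with the covariate (-1.17, adjusted p = 0.028). It also passed without 60 h replicate 1 (adjusted p = 0.043) and, just under the threshold, on the authors' scale (-1.43, adjusted p = 0.05). Without 30 h replicate 2 its value was -1.80. CLB2 passed with the covariate (-1.21, adjusted p = 0.043) and without 30 h replicate 2 (-1.88, adjusted p = 0.0047). They stood at -0.85 and -0.56 without 30 h replicate 1. The 128 cytosolic ribosomal protein genes had a median of -0.38, with 0 passing and 2 lower when adjusted over the list alone (camera adjusted p = 4.4e-18, and adjusted p = 0.35 with an estimated correlation). The median was -0.05 with centred arrays, and -0.15 and -0.61 without 30 h replicates 1 and 2. This list was not called by fry, which asks whether the genes of a list move one way without setting them against other genes (adjusted p = 0.052). RPL31B stood at -1.02 ± 0.27 (adjusted p = 0.10), and 21 of the list were lower without the 3 arrays. This gene passed without the 3 arrays (-1.12, adjusted p = 0.021), with the covariate (-0.94, adjusted p = 0.037), without 30 h replicate 2 (-1.53, adjusted p = 0.0069) and without 60 h replicate 1 (adjusted p = 0.037), and stood at -0.51 without 30 h replicate 1. In the sulphur amino acid synthesis list 1 of 29 genes rose, MET30, which is a regulator and not a synthesis enzyme. In this list 7 were higher when adjusted over the list alone. Its median was 0.43 (camera adjusted p = 7.9e-07), or 0.27 without 30 h replicate 2, and this list alone kept its call with an estimated correlation (adjusted p = 0.027). Of its genes 11 were higher without the 3 arrays, and the lowest adjusted p of any list with an estimated correlation was 0.37. Of 65 amino acid synthesis genes 3 rose and 0 fell (5 higher when adjusted over the list alone), with a median of 0.03, and the list was not called (camera adjusted p = 0.11, and adjusted p = 0.49 with an estimated correlation), with 6 rises, 2 falls and a median of -0.04 without the 3 arrays. It was called without 8 h replicate 2 (adjusted p = 0.039) and without 30 h replicate 1 (adjusted p = 0.0023).

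The hexose transporter gene HXT4 stood at -2.07 ± 0.59 (adjusted p = 0.11) and HXK2, hexokinase 2, at -1.15 ± 0.35 (adjusted p = 0.15), so neither passed. The 30 h arrays lay far apart for both, with an SD on the log2 scale of 2.16 for HXT4 and 1.03 for HXK2. Without the 3 arrays of low 5′ signal, HXT4 fell by 2.34 (adjusted p = 0.044) and HXK2 fell by 1.35 (adjusted p = 0.029). Both also passed with the covariate (-2.23 and -1.38, adjusted p = 0.027 and 0.014) and without 30 h replicate 2, at -3.60 for HXT4 (adjusted p = 9.6e-05) and -1.88 for HXK2 (adjusted p = 0.0049). Without 30 h replicate 1 the values were -0.55 and -0.42.

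Between 30 h and 60 h (n = 2 and 3 arrays), several genes for uptake and use of glucose and maltose fell and several for use of non-sugar carbon rose. HXT5 rose by 2.46 ± 0.26 (adjusted p = 5.4e-05), ACS1, acetyl-CoA synthetase, by 1.85 ± 0.30 (adjusted p = 7.4e-04), MLS1, malate synthase of the glyoxylate cycle, by 1.44 ± 0.21, and PCK1, phosphoenolpyruvate carboxykinase, by 1.14 ± 0.15. FBP1 rose by 1.88 ± 0.44 and by 2.78 without the 3 arrays of low 5′ signal. MAL31 fell by 1.13 ± 0.12 (adjusted p = 4.5e-05), and the isomaltase gene IMA1 fell by 1.51 ± 0.12 (adjusted p = 1.3e-05). The hexose transporter gene HXT1 fell by 1.28 ± 0.24 and HXT3 fell by 1.19 ± 0.19. HXK2 fell by 1.64 ± 0.35 (adjusted p = 0.0043).

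In total 866 probe sets were higher at 60 h (264 of them at least 2-fold) and 627 were lower (255 at least 2-fold). Of the 3 arrays at 60 h, 2 had low 5′ signal, so fits without them rest on 60 h replicate 3 alone. The fit without the 3 arrays of low 5′ signal gave 951 higher and 831 lower, of which 633 and 537 were shared with the full set. Centring each array on its S. cerevisiae median gave 47% higher calls against 58% here, with the median of all probe sets moved by -0.09. Without 30 h replicate 2 the counts fell to 335 and 224, and the calls of FBP1 (1.39, adjusted p = 0.12) and HXK2 (-0.91, adjusted p = 0.089) ended. A fit on the arrays of both times alone gave 113 higher and 117 lower, and HXT1 (adjusted p = 0.060), HXK2 (0.082) and FBP1 (0.088) did not pass in it.

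Of 24 measured genes of gluconeogenesis, the glyoxylate cycle and use of 2-carbon compounds, 13 rose and 2 fell (14 and 2 when adjusted over the list alone), with a median of 0.77 (camera adjusted p = 0.0017, and adjusted p = 0.42 with an estimated correlation). In the same list 17 rose and 1 fell without the 3 arrays, and its median was 0.43 without 30 h replicate 2. The maltose, maltotriose and sucrose list had 1 higher and 6 lower of 10 genes, the same numbers when adjusted over the list alone, and a median of -0.47 (camera adjusted p = 0.0056, and adjusted p = 0.15 with an estimated correlation), with 1 and 4 and a median of -0.29 without the 3 arrays. Among 15 hexose transporter genes 3 rose and 4 fell with and without the 3 arrays (4 and 6 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.52, and adjusted p = 0.62 with an estimated correlation). Of 24 trehalose and glycogen genes, 2 rose and 6 fell, as they did when adjusted over the list alone. GSY1, a glycogen synthase, fell by 1.82 ± 0.20, and of the trehalose synthase subunit genes TPS3 fell by 1.35 ± 0.15 and TPS2 fell by 1.18 ± 0.15. TPS1, the catalytic subunit of trehalose-6-phosphate synthesis, stood at -0.05 ± 0.24 (adjusted p = 0.88), and at 0.27 without the 3 arrays (adjusted p = 0.11) but -0.29 with centred arrays. This list was called at camera adjusted p = 0.029 but not with an estimated correlation (adjusted p = 0.15), without the 3 arrays (3 higher and 6 lower, adjusted p = 0.10), with the 5′ to 3′ ratio as a covariate (adjusted p = 0.089) or without 60 h replicate 1 (adjusted p = 0.068), where its median went from -0.20 to -0.10. With centred arrays the trehalose and glycogen median was -0.32 (camera adjusted p = 0.023). In glycolysis and ethanol formation 0 of 20 genes rose and 5 fell, also when adjusted over the list alone, among them HXK2. PGI1, phosphoglucose isomerase, fell by 0.67 ± 0.13 and PYK2, a pyruvate kinase, fell by 0.67 ± 0.15. PYK2 did not pass without 30 h replicate 2 (-0.45, adjusted p = 0.11), and neither PGI1 (adjusted p = 0.088) nor PYK2 (adjusted p = 0.14) did in the fit on the arrays of both times alone. The median of that list was -0.19 (camera adjusted p = 0.012, and adjusted p = 0.57 with an estimated correlation). It was not called without the 3 arrays (1 higher and 5 lower, adjusted p = 0.20), with the covariate (-0.10, adjusted p = 0.26), without 60 h replicate 1 (-0.11, adjusted p = 0.16) or by fry (adjusted p = 0.057), and its median was 0.09 on the authors' scale and -0.04 with centred arrays, where it was not called either (adjusted p = 0.40 and 0.24).

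Some genes of respiration rose over the same interval. Of 40 genes of the respiratory chain and ATP synthase, 19 rose and 0 fell (20 and 0 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 6.9e-04, and adjusted p = 0.39 with an estimated correlation). They included INH1, an inhibitor of ATP synthase, by 1.61 ± 0.19, the cytochrome oxidase gene COX9 by 1.19 ± 0.16 and the ATP synthase gene ATP17 by 1.16 ± 0.18. Respiration genes had 19 rises, 1 fall and a median of 0.30 without the 3 arrays. The tricarboxylic acid cycle had 2 rises and 0 falls among 16 genes, also when adjusted over the list alone, and was not called (camera adjusted p = 0.59, and adjusted p = 0.84 with an estimated correlation), with 3 rises without the 3 arrays. Its median was 0.09, and 0.24 without the 3 arrays, but -0.09 with centred arrays and -0.03 without 30 h replicate 2. Heme and oxygen-dependent aerobic genes had 3 rises and 1 fall among 19, also when adjusted over the list alone, with a median of 0.05, and were not called (camera adjusted p = 0.98, and adjusted p = 0.99 with an estimated correlation), with 6 and 1 and a median of 0.17 without the 3 arrays. The median was -0.02 with centred arrays and -0.07 without 60 h replicate 3.

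Most ribosomal protein transcripts fell and most proteasome transcripts rose between 30 h and 60 h. Of 128 cytosolic ribosomal protein genes, 98 fell, 0 rose and 30 did not pass (109 lower when adjusted over the list alone), with a median of -0.95 (camera adjusted p = 5.7e-39, and adjusted p = 0.15 with an estimated correlation). RPL31B fell by 2.16 ± 0.27 and RPS7B fell by 2.03 ± 0.28. The falls numbered 117 without the 3 arrays of low 5′ signal. Among 37 proteasome genes 27 rose and 0 fell (28 higher and 1 lower when adjusted over the list alone), with a median of 0.87 (camera adjusted p = 5.9e-11, and adjusted p = 0.15 with an estimated correlation). UMP1, a proteasome assembly factor, rose by 1.44 ± 0.20, and BLM10, a proteasome activator, by 1.38 ± 0.20. The rises numbered 33 without the 3 arrays.

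Several transcripts of mitosis and the cell wall fell to 60 h. EGT2 fell by 3.15 ± 0.26 (adjusted p = 1.8e-05), DSE2, a daughter cell gene, fell by 2.85 ± 0.28 (adjusted p = 3.8e-05), the wall glucanase gene SCW11 fell by 2.55 ± 0.24 and the chitinase gene CTS1 fell by 2.40 ± 0.22. Of 35 mitosis and cytokinesis genes 10 fell and 1 rose, with the same numbers when adjusted over the list alone. The polo kinase gene CDC5 fell by 1.33 ± 0.22 and the kinesin gene KIP1 rose by 1.35 ± 0.18. The median of this list was -0.26 (camera adjusted p = 0.0019, and adjusted p = 0.42 with an estimated correlation), with 1 higher and 9 lower and a median of -0.42 without the 3 arrays. That median was -0.43 with centred arrays, and -0.51 and -0.09 without 30 h replicates 1 and 2. The G1/S and DNA replication list had 5 rises and 6 falls among 35 genes, also when adjusted over the list alone, with a median of -0.05, and was not called (camera adjusted p = 0.39, and adjusted p = 0.57 with an estimated correlation), with 4 and 7 without the 3 arrays. Its median ran from -0.23 without 30 h replicate 1 to -0.02 without 30 h replicate 2. Histone genes had 4 falls and 1 rise among 8 (5 and 1 when adjusted over the list alone). HTB2 fell by 2.80 ± 0.33, while HHO1, the linker histone, rose by 0.77 ± 0.18. The histone median was -0.51 (camera adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation), and without the 3 arrays 1 rose and 5 fell. Leaving out 30 h replicate 2 ended the call of the histone list (median -0.28, adjusted p = 0.084), and leaving out 30 h replicate 1 that of HHO1 (0.52, adjusted p = 0.076), which also did not pass in the fit on the arrays of both times alone (adjusted p = 0.11). The cell wall list had 1 rise and 9 falls among 31 genes, also when adjusted over the list alone, and a median of -0.52 (camera adjusted p = 0.0017, and adjusted p = 0.52 with an estimated correlation). Its median was 0 without the 3 arrays (6 higher and 9 lower, camera adjusted p = 0.36) and -0.02 with the 5′ to 3′ ratio as a covariate (adjusted p = 0.41), and without 60 h replicate 1 the median was -0.15, also not called (adjusted p = 0.054). Without 30 h replicate 2 it was -0.30.

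Among the largest single changes to 60 h, SLF1, which codes for an RNA-binding protein, rose by 3.31 ± 0.32, with 1 of 2 arrays at 30 h above background, and NCA3 by 3.03 ± 0.52, or 1.94 without 30 h replicate 2. SUR7, a plasma membrane protein of eisosomes, fell by 3.34 ± 0.38. AGP1, a broad amino acid permease, fell by 2.88 ± 0.59 and GDH1, glutamate dehydrogenase, fell by 2.68 ± 0.57. These last changes were -1.68 and -1.56 without the 3 arrays of low 5′ signal, and GDH1 did not pass in the fit on the arrays of both times alone (adjusted p = 0.051).

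From 60 h to 80 h (n = 3 and 3 arrays), the high-affinity phosphate transporter gene PHO84 rose by 2.99 ± 0.18 (adjusted p = 1.9e-06). FKS1, the catalytic subunit of glucan synthase, rose by 2.31 ± 0.30 and FBP1 by 2.06 ± 0.39 (1.16 without the 3 arrays of low 5′ signal). The heat shock chaperone gene CPR6 fell by 2.25 ± 0.21, SSA4 fell by 1.78 ± 0.21 and HSP82 fell by 1.52 ± 0.15, with adjusted p values of 6.1e-05, 2.1e-04 and 7.4e-05. The lactate and pyruvate permease gene JEN1 rose by 0.90 ± 0.11 and HXT3 by 0.79 ± 0.17 (1.21 on the authors' scale).

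There were 503 higher (139 at least 2-fold) and 582 lower (58 at least 2-fold) probe sets at 80 h. Here too, fits without the 3 arrays of low 5′ signal keep only replicate 3 at 60 h. Leaving out the 3 arrays of low 5′ signal gave 610 higher and 605 lower, with 352 and 369 shared. On the authors' scale 86.5% of the calls were higher against 46.4% here, with the median of all probe sets moved by 0.29. Leaving out 60 h replicate 2 gave 325 higher and 361 lower, and leaving out 80 h replicates 1, 2 and 3 in turn gave 269, 233 and 307 higher and 339, 314 and 381 lower. The arrays of both times alone gave 276 and 309. Neighbouring intervals share the arrays of the time between them, so a chance deviation of the 60 h arrays would appear here and in the previous interval with opposite sign.

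Some cytosolic ribosomal protein and ribosome biogenesis transcripts rose, while most proteasome and some chaperone transcripts fell. Of 128 cytosolic ribosomal protein genes 61 rose and 0 fell (81 higher and 1 lower when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.2e-22, and adjusted p = 0.33 with an estimated correlation), RPS24B by 1.38 ± 0.16, and 98 rose without the 3 arrays. Among 65 mitochondrial ribosomal protein genes 0 rose, 11 fell and 54 did not pass (9 lower when adjusted over the list alone), with a median of -0.28 (camera adjusted p = 5.4e-04, and adjusted p = 0.58 with an estimated correlation). That list was not called without the 3 arrays (1 higher and 12 lower, median -0.10, adjusted p = 0.055) or with the 5′ to 3′ ratio as a covariate (median -0.11, adjusted p = 0.073), and its median was 0.01 on the authors' scale and -0.15 without 60 h replicate 1. Of 125 ribosome biogenesis genes 42 rose and 4 fell (53 and 4 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.3e-09, and adjusted p = 0.20 with an estimated correlation). NOG1, a nucleolar GTPase, rose by 1.22 ± 0.17 and NOP58, a nucleolar protein, by 1.23 ± 0.28 (0.79 with the covariate), and 45 rose and 3 fell without the 3 arrays. The biogenesis median was 0.70 on the authors' scale. In the proteasome list 23 of 37 genes fell and 1 rose (27 and 1 when adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.3e-09, and adjusted p = 0.19 with an estimated correlation). UMP1 fell by 1.23 ± 0.18, RPN6 fell by 1.11 ± 0.15 and PUP2 fell by 1.01 ± 0.11, and 26 fell and 1 rose without the 3 arrays. Among 32 chaperone genes 15 fell and 3 rose (17 and 3 when adjusted over the list alone), with a median of -0.46 (camera adjusted p = 7.3e-05, and adjusted p = 0.37 with an estimated correlation), and 15 fell and 2 rose without the 3 arrays. The chaperone median was -0.23 on the authors' scale.

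Some genes of a list tied to oxygen limitation rose to 80 h. Of 24 such genes 8 rose and 0 fell, also when adjusted over the list alone, with a median of 0.53 (camera adjusted p = 4.1e-05, and adjusted p = 0.19 with an estimated correlation), and 10 rose without the 3 arrays. The median of this list was 0.24 without the 3 arrays, 0.23 with the 5′ to 3′ ratio as a covariate and 0.32 without 60 h replicate 1. UPC2, a regulator of sterol uptake, rose by 1.45 ± 0.25 (0.75 without the 3 arrays) and SUT1, another regulator of sterol uptake, by 1.06 ± 0.20 (0.65 without the 3 arrays). In the cell wall list 7 of 31 genes rose and 0 fell (13 higher when adjusted over the list alone), with a median of 0.56 (camera adjusted p = 2.3e-05, and adjusted p = 0.46 with an estimated correlation). It held FKS1 and the glucan synthesis gene KRE6, which rose by 1.84 ± 0.46, by 0.86 without the 3 arrays and by 1.80 without 80 h replicate 2 (adjusted p = 0.053). Of this list 8 genes rose without the 3 arrays, where its median was 0.25, and the median was 0.07 with the covariate. The amino acid and peptide permease list had 8 rises and 0 falls among 23 genes (12 higher when adjusted over the list alone) and a median of 0.68 (camera adjusted p = 4.1e-05, and adjusted p = 0.46 with an estimated correlation), with 7 and 2 and a median of 0.29 without the 3 arrays, and 0.37 without 60 h replicate 1. It was not called with the 5′ to 3′ ratio as a covariate (median 0.25, adjusted p = 0.073). The branched-chain amino acid permease gene BAP2 rose by 1.74 ± 0.36, and by 0.58 without the 3 arrays.

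From 80 h to 102 h (n = 3 and 3 arrays), most seripauperin genes and some chaperone and ribosome biogenesis genes rose. The seripauperin gene PAU17 rose by 1.17 ± 0.20 (adjusted p = 0.0028), the heat shock gene HSP30 by 0.99 ± 0.13 (adjusted p = 0.0010, and 0.63 on the authors' scale) and the Hsp40 chaperone gene YDJ1 by 0.90 ± 0.18 (adjusted p = 0.0059). RHO1, a GTPase of cell wall synthesis, rose by 1.88 ± 0.40, MCM1, a transcription factor, by 1.67 ± 0.28, PHO84 by 1.13 ± 0.18 and PCK1 by 0.97 ± 0.14 (0.62 on the authors' scale). The acetate transporter gene ADY2 fell by 1.48 ± 0.26 (adjusted p = 0.0033), SPL2, a regulator of phosphate transport, fell by 1.79 ± 0.27 and DIP5, a permease for acidic amino acids, fell by 1.73 ± 0.27. No array of these times had low 5′ signal.

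In all 405 probe sets were higher (69 at least 2-fold) and 446 lower (81 at least 2-fold). Without the 3 arrays of low 5′ signal, which enter only through the shared spread estimate, 1053 were higher and 1231 lower, including all 405 and all 446. On the authors' scale 7.89% of the calls were higher against 47.6% here, with the median of all probe sets moved by -0.27, and 59.1% were higher with each array centred on its S. cerevisiae median. Leaving out 60 h replicate 1 gave 622 and 731, and the arrays of both times alone gave 1201 and 1387. Leaving out 80 h replicates 1, 2 and 3 gave 259, 181 and 185 higher and 277, 197 and 182 lower, and leaving out 102 h replicates 1, 2 and 3 gave 228, 200 and 175 higher and 242, 242 and 204 lower.

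Of 13 measured seripauperins, a family of cell wall mannoproteins known from anaerobic and stressed yeast, 9 rose and 0 fell, also when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 5e-06, and adjusted p = 0.46 with an estimated correlation). Members of this family are near-identical copies and most of their probe sets are marked by the manufacturer as shared between transcripts, so the values of single members are uncertain. Among 32 chaperone genes 11 rose and 0 fell (15 higher when adjusted over the list alone), with a median of 0.38 (camera adjusted p = 5e-06, and adjusted p = 0.46 with an estimated correlation). Of 125 ribosome biogenesis genes 23 rose, among them BUD20 by 1.21 ± 0.13, and 2 fell (25 and 2 when adjusted over the list alone), with a median of 0.23 (camera adjusted p = 9.4e-06, and adjusted p = 0.46 with an estimated correlation). Cytosolic ribosomal protein genes had 20 rises and 0 falls among 128, also when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 2.9e-04, and adjusted p = 0.93 with an estimated correlation), and were not called by fry (adjusted p = 0.30). Of 65 mitochondrial ribosomal protein genes 15 rose and 0 fell (19 higher and 1 lower when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 1.6e-05, and adjusted p = 0.77 with an estimated correlation), MRP20 by 1.46 ± 0.26 and MRPL19 by 1.12 ± 0.19, and were not called by fry (adjusted p = 0.074). On the authors' scale the medians were 0.43 for seripauperins and 0.16 for chaperones, and turned to -0.10 for ribosome biogenesis, -0.04 for cytosolic and -0.10 for mitochondrial ribosomal proteins. The cytosolic median was 0.29 with centred arrays. The list of gluconeogenesis, the glyoxylate cycle and 2-carbon use had 7 falls and 1 rise among 24 genes (8 and 1 when adjusted over the list alone) and a median of -0.32 (camera adjusted p = 0.019, and adjusted p = 0.86 with an estimated correlation). Its falls included ADY2 and its rise was PCK1. The glycerol transporter gene STL1 fell by 1.09 ± 0.26 and IDP3, an isocitrate dehydrogenase of peroxisomes, fell by 0.87 ± 0.16. STL1 did not pass without 80 h replicate 1 (-1.02, adjusted p = 0.051), 80 h replicate 2 (-0.97, adjusted p = 0.068) or 102 h replicate 2 (-0.85, adjusted p = 0.061). That list was not called on the authors' scale (-0.53, adjusted p = 0.19), with centred arrays (-0.19, adjusted p = 0.11) or by fry (adjusted p = 0.098).

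Over the whole course, from 8 h to 102 h (n = 3 and 3 arrays), several genes of gluconeogenesis rose and most genes of mitosis fell. AQY1, a water channel, rose by 5.63 ± 0.64 (adjusted p = 1.7e-05), NCA3 by 5.62 ± 0.47 (adjusted p = 1.8e-06), PHO84 by 4.93 ± 0.18 (adjusted p = 3.1e-09), FBP1 by 4.19 ± 0.39 (adjusted p = 4.3e-06) and PCK1 by 2.67 ± 0.14 (adjusted p = 6.7e-08). AIM20 fell by 4.40 ± 0.25, EGT2 fell by 3.63 ± 0.24 and HOF1, a cytokinesis protein, fell by 3.45 ± 0.41, with 2 of 3 arrays at 102 h above background. SWI5, a transcription factor of mitotic exit, was above background on 1 of 3 arrays at 102 h, so the size of its fall is set partly by background. It fell by 3.70 with the usual floor and fell by 2.60 with values raised to the background threshold (adjusted p = 4.5e-04 and 2.1e-04). The phosphate response list, which holds PHO84, had 5 rises and 3 falls among 19 genes, also when adjusted over the list alone, with a median of 0.21, and was not called (camera adjusted p = 0.14, and adjusted p = 0.36 with an estimated correlation), with 7 and 4 without the 3 arrays. It was called by fry (adjusted p = 5.6e-05), and its median was 0.07 on the authors' scale.

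The 102 h arrays had 1155 higher (480 at least 2-fold) and 1525 lower (494 at least 2-fold) probe sets than the 8 h arrays. Without the 3 arrays of low 5′ signal, 1 of them at 8 h, 1525 were higher and 1799 lower, with 1131 and 1474 shared.

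Among carbohydrate genes HXT5 rose by 2.00 ± 0.24 and the alcohol dehydrogenase gene ADH2, which serves ethanol use, by 1.91 ± 0.25. HXT4 fell by 3.40 ± 0.53, IMA1 fell by 1.38 ± 0.10, MAL31 fell by 0.96 ± 0.10, HXT1 fell by 0.88 ± 0.22 and HXK2 fell by 1.09 ± 0.32. PDC1, the main pyruvate decarboxylase, stood at -0.25 ± 0.086 (adjusted p = 0.027), a value of 0.06 on the authors' scale and 0.17 with centred arrays, so its direction depends on the scaling. It did not pass without 8 h replicate 1 or 2 (adjusted p = 0.092 and 0.063) or without 102 h replicate 1, 2 or 3 (adjusted p = 0.056, 0.060 and 0.088), nor without an intensity trend (adjusted p = 0.062). Of 24 genes of gluconeogenesis, the glyoxylate cycle and 2-carbon use 12 rose and 2 fell, also when adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.0046, and adjusted p = 0.33 with an estimated correlation), and 14 and 2 without the 3 arrays. Trehalose and glycogen genes had 4 rises and 11 falls among 24, also when adjusted over the list alone, with a median of -0.35, and the list was called by fry (adjusted p = 1.7e-06) but not by camera (camera adjusted p = 0.084, and adjusted p = 0.22 with an estimated correlation). PGM1, a phosphoglucomutase, fell by 2.46 ± 0.27, GSY1 fell by 2.25 ± 0.18 and TPS3 fell by 1.66 ± 0.13, and without the 3 arrays 5 of the list rose and 11 fell. Glycolysis and ethanol formation had 2 rises and 9 falls among 20 genes, also when adjusted over the list alone (camera adjusted p = 0.19, and adjusted p = 0.64 with an estimated correlation), with 2 and 11 without the 3 arrays. PYK2 fell by 1.49 ± 0.14 and PFK1, a phosphofructokinase subunit, fell by 1.12 ± 0.14, while the minor pyruvate decarboxylase gene PDC6 rose by 1.67 ± 0.31. The median of that list was -0.12, but 0.13 on the authors' scale and 0.23 with centred arrays, and -0.25 with the 5′ to 3′ ratio as a covariate, where the list was called (adjusted p = 0.035). It was also called by fry (adjusted p = 0.043), and its median was -0.21 without the 3 arrays. Respiratory chain and ATP synthase genes had 21 rises and 1 fall among 40 (21 and 2 when adjusted over the list alone), such as COX4 by 1.19 ± 0.15, with a median of 0.53 (camera adjusted p = 9.6e-05, and adjusted p = 0.25 with an estimated correlation) and 30 and 2 without the 3 arrays.

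Most ribosome biogenesis transcripts rose and most cytosolic ribosomal protein transcripts fell. Of 125 ribosome biogenesis genes 92 rose and 4 fell (93 and 5 when adjusted over the list alone), with a median of 0.86 (camera adjusted p = 5.4e-19, and adjusted p = 0.10 with an estimated correlation). NSR1, a nucleolar protein, rose by 2.16 ± 0.25 and REI1, a factor of 60S subunit maturation, by 1.98 ± 0.17. Ribosome biogenesis had 102 rises and 6 falls without the 3 arrays. Of 128 ribosomal protein genes 92 fell and 0 rose (95 lower when adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.3e-11, and adjusted p = 0.34 with an estimated correlation). RPL31B fell by 2.26 ± 0.25 and RPS26B fell by 1.79 ± 0.24, and 104 of the list fell without the 3 arrays.

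Most genes of mitosis and all histone genes fell. In the mitosis and cytokinesis list 25 of 35 genes fell and 1 rose, also when adjusted over the list alone, with a median of -1.02 (camera adjusted p = 3.3e-07, and adjusted p = 0.22 with an estimated correlation), and 24 and 1 without the 3 arrays. G1/S and DNA replication had 6 rises and 14 falls among 35 genes, also when adjusted over the list alone, with a median of -0.37, and was not called (camera adjusted p = 0.44, and adjusted p = 0.64 with an estimated correlation), with 9 and 15 without the 3 arrays. It was called by fry (adjusted p = 0.0048), and its median was -0.21 with centred arrays. All 8 histone genes fell, with and without those arrays and when adjusted over the list alone, with a median of -0.91 (camera adjusted p = 7e-04, and adjusted p = 0.25 with an estimated correlation). HTB2 fell by 2.70 ± 0.30 and HHT2 fell by 1.02 ± 0.16.

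Sterol genes and genes of the list tied to oxygen limitation were mostly higher at the end. Of 25 ergosterol synthesis genes 16 rose and 3 fell, also when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 3.1e-04, and adjusted p = 0.22 with an estimated correlation) and 18 and 3 without the 3 arrays. HES1 rose by 1.32 ± 0.20, ERG3, the C-5 sterol desaturase, by 1.28 ± 0.12 and ERG25, the C-4 methyl sterol oxidase, by 1.05 ± 0.11. The fatty acid desaturase gene OLE1 rose by 1.09 ± 0.20. Among 24 oxygen-limitation genes 14 rose and 5 fell (14 and 6 when adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.0046, and adjusted p = 0.22 with an estimated correlation) and 15 and 5 and a median of 0.57 without the 3 arrays, and 0.45 with the 5′ to 3′ ratio as a covariate. PDR11, a sterol uptake transporter, rose by 2.79 ± 0.17, while ANB1, a hypoxic translation factor gene, fell by 1.08 ± 0.17. ROX1, a repressor of hypoxic genes that is also on the list, rose by 1.78 ± 0.13. A rise of that repressor does not by itself speak for oxygen limitation. Of 13 seripauperins 11 rose and 0 fell, also when adjusted over the list alone, with a median of 1.67 (camera adjusted p = 3.3e-07, and adjusted p = 0.21 with an estimated correlation), and 12 rose without the 3 arrays. PAU5 gave 2.17 ± 0.18 and PAU2 1.87 ± 0.16, both from probe sets shared with near-identical copies.

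Stress genes split by member. Of 38 genes under Msn2 and Msn4, 17 rose and 10 fell, also when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.037, and adjusted p = 0.40 with an estimated correlation) and 18 and 8 and a median of 0.23 without the 3 arrays. GRE1 rose by 3.45 ± 0.44, SIP18 by 2.54 ± 0.34 and HSP26 by 2.18 ± 0.42. HSP12, with mean signals from 8930 to 11600 through the course, stood at -0.25 ± 0.073 (adjusted p = 0.012), but at 0.20 on the authors' scale and 0.30 with centred arrays. Genes of folding in the endoplasmic reticulum had 2 rises and 13 falls among 26 (3 and 13 when adjusted over the list alone), and EUG1, a protein disulphide isomerase, fell by 1.44 ± 0.21. Their median was -0.51 (camera adjusted p = 0.047, and adjusted p = 0.22 with an estimated correlation), with 3 and 17 without the 3 arrays. That call ended when any of 8 h replicate 2, 8 h replicate 3, 30 h replicate 1, 30 h replicate 2, 60 h replicate 2, 102 h replicate 1 or 102 h replicate 3 was left out, at adjusted p values of 0.087, 0.070, 0.060, 0.060, 0.051, 0.065 and 0.052. It also ended without an intensity trend (adjusted p = 0.051) and in a fit on the arrays of both times alone (adjusted p = 0.065). The actin gene ACT1, a common loading control, stood at -0.30 ± 0.088 (adjusted p = 0.013), at -0.05 on the authors' scale and at 0.06 with centred arrays. Without 8 h replicate 3 it did not pass (-0.26, adjusted p = 0.054).

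**Figure D3:**
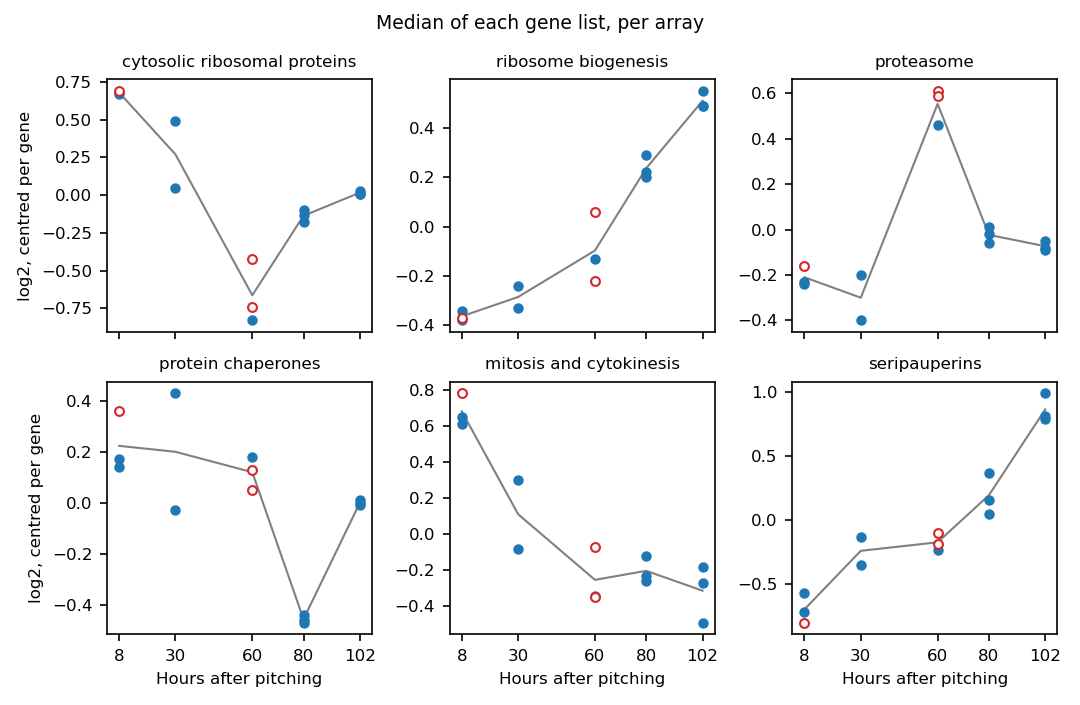
Median over the members of 6 gene lists of the log2 signal centred per gene (vertical axes, each with its own range) against hours after pitching, 1 point per array, with open points for the 3 arrays of low 5′ signal and lines through the group means. The proteasome medians at 60 h lie between 0.46 and 0.61, above all other times, and those of the ribosomal proteins at 60 h between -0.83 and -0.42, below all other times.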

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

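The test of the unnamed probe sets over time was chosen after their signals were seen. Outside the probe sets of S. cerevisiae genes, 199 of 3517 unnamed probe sets (5.66%) were above background on all 14 arrays. Of the 424 unnamed probe sets that passed the filter on dim signals, 163 passed the F-test over time. No gene was assigned to them, and the source of their signal was not tested.

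Among 1746 probe sets for genes of another organism, 3 (0.172%) were above background on all arrays. Their signals ran from 24.2 to 50.7 for srp2, from 23.2 to 80.5 for spi1 and from 34.5 to 142 for hta1, against a threshold of 22.1. These names were taken from the annotation after the signals were seen.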

How the results depend on the processing

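Leaving out the 3 arrays of low 5′ signal, the 5′ to 3′ ratio as a covariate and the other background were chosen after the data were seen, and the other alternatives were planned. A block for chip lot, station or scan day was not run. Of 155 values of named genes, 120 kept their direction and their side of the threshold under every alternative run. Of 58 gene list results 4 did, and 35 did under every alternative but the estimated correlation. Of those 4, only sulphur amino acid synthesis from 8 h to 30 h was a call. Without the 3 arrays of low 5′ signal it was not called with an estimated correlation. The rest were lists not called in the main fit. They were hexose transporters and G1/S and DNA replication from 30 h to 60 h, and aroma from 8 h to 102 h. Many named genes were picked as large changes past the test in these same data. Their share therefore does not describe the calls in general. Over all alternatives 199 gene values were weaker, 19 stronger, 3 moved and 5 reversed, and for lists 90 were weaker, 11 stronger, 12 moved and 0 reversed, where the direction of a list is that of its set test. Its median turned in 22 list values. Reversed from a fall were HSP12 from 8 h to 102 h (0.20 on the authors' scale and 0.30 with centred arrays), PDC1 (0.06 and 0.17) and ACT1 (0.06 with centred arrays). Other floors, filters on dim probe sets and the other background moved no count of changed probe sets by over 1.5 times. Dim probe sets stay limited by the background.

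On the authors' scale 29 probe sets were lower at 30 h than at 8 h, 1123 were higher and 176 lower at 80 h than at 60 h, and 122 were higher and 1424 lower at 102 h than at 80 h. The scale moved the median of all probe sets by -0.14, 0.29 and -0.27 in these comparisons. With centred arrays 286 were lower at 102 h than at 80 h, and without an intensity trend 4 were lower at 30 h. A threshold of 0.01 gave, as higher and lower counts in time order, 1 and 0, 435 and 370, 197 and 257, and 142 and 143, which follows from the stricter threshold. Fits on the arrays of both times alone, with fewer samples for the spread, gave 0 and 0, 113 and 117, and 276 and 309, but 1201 and 1387 from 80 h to 102 h, times with no array of low 5′ signal. Without the 3 arrays of low 5′ signal there were 215 and 219 changes to 30 h, and 1053 and 1231 from 80 h to 102 h. With the ratio as a covariate there were 187 and 198 to 30 h, 944 lower at 60 h, and 921 and 1106 from 80 h to 102 h. Beyond these constructions, the cause was not tested.

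Leaving out each array in turn, the F-test gave 3251 to 3973 probe sets. The counts of higher probe sets ran from 0 to 126 at 30 h, 335 to 1053 at 60 h, 233 to 724 at 80 h, 175 to 622 from 80 h to 102 h and 937 to 1366 from 8 h to 102 h. Those of lower ones ran from 0 to 175, 224 to 782, 314 to 817, 182 to 731 and 1269 to 1736. Where 30 h kept 1 array, it is assumed to vary like the other groups. The same is assumed for 60 h, which keeps replicate 3 alone in fits without the 3 arrays of low 5′ signal.

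With the replicate number as a block, 1 probe set was higher and 0 lower at 30 h than at 8 h, and the other counts stayed within 1.5 times, with 3858 past the F-test, 970 and 720 at 60 h, 587 and 664 at 80 h, 434 and 486 from 80 h to 102 h, and 1229 and 1569 from 8 h to 102 h. Whether the numbers pair the samples is not settled by these values. Deviations from the group means correlated above 0.1 in 4 of 26 same-numbered pairs (-0.136 to 0.74). The range was -0.703 to 0.618 in 52 differently numbered pairs, for which no such count was made. Of 14 arrays, 6 correlated best with an array of their own number. The block fit is therefore not set aside.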

Other observations

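Tests without the 3 arrays of low 5′ signal, the fit with the 5′ to 3′ ratio as a covariate and the comparison of this ratio between the 30 h arrays were chosen only after the results were seen. Several genes for vitamin B6 and B1 were higher at 60 h than at 30 h and at 80 h. SNO1, a gene of pyridoxine synthesis, rose by 2.80 ± 0.30 from 30 h to 60 h and fell by 2.17 ± 0.26 to 80 h, and its partner SNZ1 rose by 1.57 ± 0.22 and fell by 1.01 ± 0.19. THI73, a thiamine-regulated transporter gene, rose by 2.23 ± 0.24 to 60 h. Of 18 measured vitamin genes 8 rose and 0 fell to 60 h (9 higher when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation) and 7 rises and a median of 0.40 without the 3 arrays. To 80 h 6 fell and 1 rose (7 and 1 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0063, and adjusted p = 0.26 with an estimated correlation) and 4 falls, 0 rises and a median of -0.24 without the 3 arrays, and -0.06 on the authors' scale. Several genes of purine synthesis and of the 1-carbon metabolism that feeds it fell from 60 h to 80 h. GCV2, of the glycine cleavage system, fell by 1.76 ± 0.15 (adjusted p = 2.8e-05), MTD1 fell by 1.30 ± 0.20 and ADE4, the first enzyme of purine synthesis, fell by 1.21 ± 0.13. In the purine and pyrimidine synthesis list 15 of 28 genes fell and 3 rose (15 and 4 when adjusted over the list alone), and 16 and 4 without the 3 arrays. This list had a median of -0.52 (camera adjusted p = 1.6e-04, and adjusted p = 0.33 with an estimated correlation). Its median was -0.23 on the authors' scale. Fatty acid synthesis and desaturation had 7 falls and 0 rises among 16 genes from 30 h to 60 h, also when adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0024, and adjusted p = 0.24 with an estimated correlation) and 6 falls, 2 rises and a median of -0.21 without the 3 arrays, and -0.25 with the 5′ to 3′ ratio as a covariate. The elongase gene ELO3 fell by 2.46 ± 0.28 and ELO1 fell by 1.23 ± 0.19, though ELO1 did not pass in a fit on the arrays of both times alone (adjusted p = 0.056). Beta-oxidation had 6 rises and 0 falls among 18 genes (7 higher when adjusted over the list alone), FOX2 by 1.31 ± 0.23, with a median of 0.46 (camera adjusted p = 0.0028, and adjusted p = 0.47 with an estimated correlation) and 10 rises without the 3 arrays, and FOX2 did not pass in that fit (adjusted p = 0.060). The beta-oxidation median was 0.24 without 30 h replicate 2.

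Several mating genes rose from 30 h to 60 h, FAR1 by 1.41 ± 0.23 and KAR4 by 1.01 ± 0.14. MFA1, a precursor of a-factor, was above background on 1 of 2 arrays at 30 h, so the size of its rise is set partly by background. It rose by 2.80 with the usual floor and by 2.59 with values raised to the background threshold (adjusted p = 4.6e-04 and 4.4e-04). Of 22 genes 8 rose and 0 fell, also when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.0072, and adjusted p = 0.51 with an estimated correlation). The list was not called without the 3 arrays of low 5′ signal (4 rises, median 0.34, adjusted p = 0.10), with the 5′ to 3′ ratio as a covariate (0.36, adjusted p = 0.061) or without 30 h replicate 2 (0.38, adjusted p = 0.058), and its median was 0.32 with centred arrays. FLO11, a cell surface adhesin, rose by 1.78 ± 0.24 over the same interval, while its flocculation list of 9 genes had 2 rises and 1 fall, also when adjusted over the list alone, and was not called (camera adjusted p = 0.42, and adjusted p = 0.57 with an estimated correlation), with 3 and 1 without the 3 arrays. It was called by fry (adjusted p = 0.0011). From 8 h to 102 h ARO9 fell by 2.66 ± 0.16 and EEB1, which forms ethyl esters, rose by 1.52 ± 0.14, while ATF1, which forms acetate esters, stood at -0.15 ± 0.13 (adjusted p = 0.36). The aroma list of 20 genes had 7 rises and 4 falls, also when adjusted over the list alone (camera adjusted p = 0.44, and adjusted p = 0.64 with an estimated correlation), with 8 and 6 without the 3 arrays. DAL7, of allantoin breakdown, fell by 3.28 ± 0.33 from 8 h to 102 h, and DAL3 was at least 5.46-fold lower, being below background on all 3 arrays at 102 h (adjusted p = 3.5e-06). Genes under nitrogen catabolite repression had 2 rises and 13 falls among 34, also when adjusted over the list alone (camera adjusted p = 0.12, and adjusted p = 0.33 with an estimated correlation), and were called by fry (adjusted p = 5e-04), with the 5′ to 3′ ratio as a covariate (adjusted p = 0.016) and without the 3 arrays (5 and 20, adjusted p = 0.029), but not with an estimated correlation without the 3 arrays (adjusted p = 0.54). Iron uptake genes had 8 rises and 0 falls among 22, also when adjusted over the list alone, TIS11 by 1.64 ± 0.31 (2 of 3 arrays at 8 h above background) and FTR1 by 0.95 ± 0.21, with a median of 0.48 (camera adjusted p = 0.034, and adjusted p = 0.33 with an estimated correlation). That list was not called without the 3 arrays (9 and 1, adjusted p = 0.081), with the covariate (adjusted p = 0.11) or without 8 h replicate 1 (adjusted p = 0.083), nor over probe sets above background on every array (adjusted p = 0.071).

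The median of the ribosomal protein transcripts was lower at 60 h than at 30 h on every 60 h array, by list medians between -1.09 and -0.67 against the mean of the 30 h arrays, which themselves stood at -0.24 and 0.24. A candidate explanation is loss of RNA from 5′ ends in 60 h replicates 1 and 2. It predicts little change on 60 h replicate 3, whose 5′ to 3′ ratio lay with the other arrays, and the value there was -1.09, below a bound of -0.5 set before the result was seen. With the 5′ to 3′ ratio as a covariate the median over all arrays was -1.04, which argues against such loss as the whole cause. Handling shared by all 60 h samples cannot be separated from the stage of the fermentation, which also stays open.

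Proteasome transcripts stood at 0.94, 0.89 and 0.80 on the 60 h arrays against the mean of the 30 h arrays, and at 0.29 to 0.34 on the 80 h arrays. Loss of RNA from 5′ ends in 60 h replicates 1 and 2 could raise them through the normalization, but 60 h replicate 3 alone gave 0.80, past a bound of 0.4 set beforehand. The covariate fit gave 0.84. The stage of the fermentation and handling shared by the 60 h samples remain open and were not tested.

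The array 30 h replicate 2 lay nearer to 8 h than its partner did, at 13.2% of the way from 8 h to 80 h against 41.9% for 30 h replicate 1 and 3.26% for an 8 h array taken the same way. Different RNA quality is unlikely as the source, since the mean log2 5′ to 3′ ratios of both differed by 0.0786. Another candidate is that 30 h replicate 2 was an 8 h sample under a wrong label. Its deviations from the line between 8 h and 80 h should then not follow those of 30 h replicate 1. They correlated at 0.427 over probe sets, which are not independent replicates, with separate 8 h and 80 h arrays for each. The 8 h arrays used, replicates 2 and 3, correlated at 0.994, so deviations they share enter both values. No known 8 h array was put through the same step, so this cannot exclude a wrong label. Handling shared by both 30 h arrays could also raise the correlation of 0.427 and was not tested. A wrong label and uneven sampling of the vessel stay open.

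In 100 random assignments of the 14 arrays to times, the real one included, 1 gave as many probe sets past the F-test as the real. The real assignment had 3657 and the highest other gave 433, so arrays of a time resembled each other more than random groups did. Because all samples came from 1 vessel, this cannot separate time from handling shared by the arrays of a time. For the comparisons of 3 arrays against 3, the 10 splits cannot give a share under 0.05. Their real values and highest others were 1085 and 0 for 60 h and 80 h, 851 and 0 for 80 h and 102 h, and 2680 and 0 for 8 h and 102 h. Every other split mixes both times in each group, which puts any difference between the times into the spread. The values of 0 follow largely from this and are no support.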
